A study of Mus musculus with 6 samples.

How the data were processed

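Gene expression was measured in embryoid bodies, the cell aggregates in which mouse embryonic stem cells differentiate, grown from the Hoxb4i line, whose doxycycline-inducible cassette carries HOXB4. The embryoid bodies were seeded at 3500 cells/ml and harvested on day 6, either after 48 hours with doxycycline at 2 µg/ml from day 4 or without induction. Each of the 2 groups has 3 biological replicates, per the series' design text, named experiments A, B and C in both groups, so that 6 arrays were used. Per the labels, 4.3 µg of total RNA was labelled in 1 cycle and hybridized to the Affymetrix Mouse Genome 430 2.0 array. Doxycycline without the HOXB4 cassette is not among the 6 samples, so the comparison does not separate HOXB4 from doxycycline itself.

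The authors deposited 1 intensity per probe set and array, which the submitters' processing notes credit to MAS5; the MAS5 version and the probe annotation behind it are not given in the sources used here. The values were linear and above 0, and the mean left after trimming 2% off each end was 500 on every array, so the arrays had been scaled to 1 target before deposit. The table holds no detection calls, and the number of arrays limits the precision. No further normalization was applied. Of 45101 probe sets, 64 Affymetrix control probe sets were left out of the tests.

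From these values, log2(signal + 18.8) was computed, where 18.8 is the 20th percentile of all values; fold changes therefore refer to the signal with this offset and are smaller than ratios of the signals for dim probe sets. Probe sets whose mean over the 6 arrays lay below the 40th percentile were not tested, which left 27022 of 45037. Genes were named from GEO's platform annotation, which can be old, with symbols updated through the Entrez ID in a RefSeq gene table of assembly GRCm38.p6; a current symbol was found in this way for 34754 of the 34958 probe sets named for 1 gene. Another 932 probe sets were named for several genes and 9160 were not named, and no gene was read from these. A gene named by several tested probe sets was represented by the one with the highest mean, which gave 12443 genes.

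The groups were compared with limma 3.58.1 in R 4.3.3 (a group means model, empirical Bayes moderation with an intensity trend, Benjamini-Hochberg adjustment over all tested probe sets, threshold 0.05, two-sided). The fit without the experiment letter was fixed as the first choice, and the fit with the letter as a replicate block as an alternative. Whether the letters pair the arrays was checked before the fits were compared: the labels name a shared experiment for each letter. The deviations from the group means correlated at 0.44 to 0.67 across probe sets for arrays with the same letter. For arrays with different letters they correlated at -0.76 to -0.11, but deviations within a group cancel out, which pulls these values down. By these deviations 6 of 6 arrays matched the other array of their own experiment best. By the log2 signals themselves, the induced array of A correlated best with the induced array of B (0.948, against 0.944 with the uninduced array of A). The letters were therefore taken to pair the arrays, and blocked values are given where they change a call or a count by over 1.5 times. Intervals of single genes, and the choice of genes by smallest p, come from the fit without the block. That fit counts differences between experiments as spread.

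The 23 gene lists were fixed before the data were examined: haematopoietic stem and progenitor regulators, erythroid and haem synthesis, myeloid and macrophage, megakaryocyte and platelet, endothelial, pluripotency, primitive streak and early mesoderm, cardiac, visceral and definitive endoderm, neural and neural crest, mesenchyme with smooth muscle and fibroblast, Hox cluster, Hox cofactors of the TALE homeobox class, cell cycle, Wnt targets and ligands, Notch, BMP and TGF-beta, FGF, TNF and NF-kappaB, integrated stress response, hypoxia and glycolysis, immediate early and heat shock, and p53 targets. They hold 588 distinct symbols, of which 555 were named on the array and 448 were tested. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without reference to other genes, were the alternatives.

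The rule for named genes, also fixed beforehand, took every Hoxb4 probe set; the 12 genes with the largest rise and the 12 with the largest fall past the threshold in all 3 experiments, or, where no gene passed in a direction, the 5 with the smallest p; up to 3 members of each list with the smallest p; and the reference genes Actb and Gapdh. Gapdh had no tested probe set named for it alone, so its value is not reported here. Array quality was read from the 3' and 5' control probe sets of Actb and Gapdh.

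A comparison of the experiments with one another (an F test of the letter beside doxycycline, and pairwise contrasts from the same limma fit) was added after the data had been seen, and the genes named in it were chosen after their values were seen, from the 20 with the smallest p and the 4 with the smallest p in each list. Where both arrays of the lower experiment lay below the filter limit of 6.19 log2 units, that limit was put in their place and the difference is given as a bound, while the p refers to the values themselves. Alternatives that were tried are quantile normalization, median centring, offsets of 1 and 60.7 (the 40th percentile), no filter, a filter at the 60th percentile, the replicate block, no intensity trend, an added fold limit of 1.5, the mean of all probe sets of a gene, and leaving out each array and, added later, each experiment.

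The scripts were tested on simulated data with the spread of these 6 arrays, 27022 probe sets and 200 changed probe sets. Without the block, 0% of changes of 2-fold, 27.5% of changes of 4-fold and 74.5% of changes of 8-fold passed the threshold. With the block the shares were 46.5%, 95.5% and 99.5%, with 10, 15 and 19 false calls. The simulated noise was independent between probe sets and had the same spread on all arrays. In the data the SD of the doxycycline difference was 0.646 in A and 0.437 in B, so these shares are only approximate. Figures were drawn with matplotlib 3.10.9 from the same tables.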

Results

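Transcript levels were measured on 6 arrays of day 6 embryoid bodies made from mouse embryonic stem cells that carry a doxycycline-inducible HOXB4 cassette. In each of the experiments A, B and C, embryoid bodies given doxycycline for 48 hours from day 4 stood beside embryoid bodies that were not induced, so that each group held 3 arrays. The median signal per array lay between 92.0 and 108.6. The uninduced array of experiment A stood apart in quality: its ratio of the 3' to the 5' control signal was 2.88 for Actb and 1.08 for Gapdh, against 1.26 to 1.48 and 0.834 to 0.903 on the other 5 arrays. The 3' control signal of Tfrc, the transferrin receptor, was 146 on that array and 535 to 1114 on the others. On 53.8% of the tested probe sets that array had either the highest or the lowest of the 6 values; for the induced array of the same experiment this share was 17.7%.

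The arrays of B and those of C grouped by experiment and not by doxycycline, while those of A did so less clearly. The experiment accounted for 71.7% of the sum of squares over the tested probe sets and the induction for 9.54%. Both shares include chance differences, which weigh more for the experiment because it has more levels. The 9.54% therefore does not by itself show an effect of the induction. The first principal component, with 44.5% of the variance, set experiments B and C apart. The second, with 33.3%, mainly set the uninduced array of A, at -97.2, apart from the other arrays, at -19.2 to 44.2. The induced and uninduced arrays lay closer to one another in B and C than in A. The induced array of A was about as close to the induced array of B as to the uninduced array of A. The SD of the log2 differences was 0.632 and 0.646 for these pairs.

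**Figure D1:**
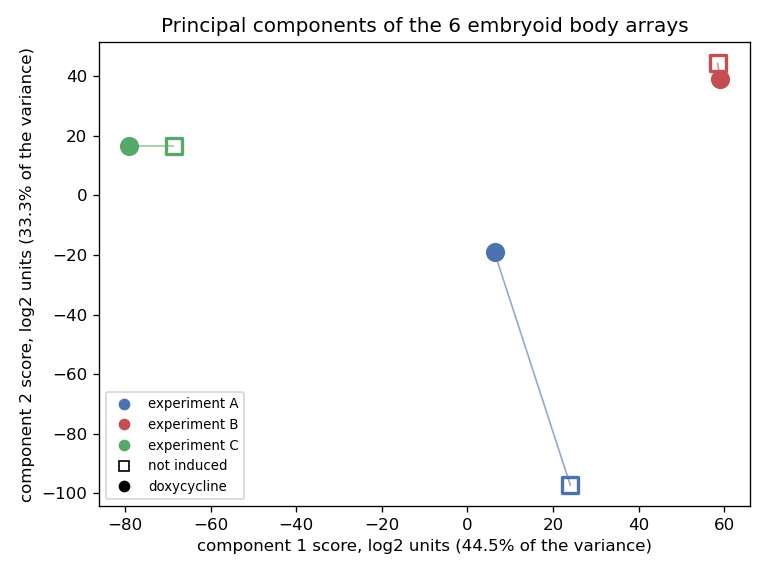
Scores of the 6 arrays on principal components 1 and 2 of the log2 signals (axes in log2 units, with 44.5% and 33.3% of the variance); colour gives the experiment, squares are uninduced and circles induced arrays, and a line joins the arrays of each experiment. Experiments B and C lie at opposite ends of component 1, and the uninduced array of A lies at -97.2 on component 2.

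The first comparison asked which genes respond when HOXB4, a homeodomain transcription factor of blood stem cells, is induced in embryoid bodies. Hoxb4 itself had a higher mean signal with doxycycline on both of its probe sets, by less than the test could tell from the spread between replicates. On probe set 1451761_at the signal was 93.3 ± 40.6 (SD, n = 3) without and 140.5 ± 31.0 (SD, n = 3) with doxycycline, a log2 fold change of 0.57 with a 95% confidence interval of -0.35 to 1.49 (adjusted p = 1). On probe set 1460379_at it was 119.6 ± 118.3 (SD, n = 3) without and 182.8 ± 68.45 (SD, n = 3) with doxycycline, a log2 fold change of 0.86 with an interval of -0.60 to 2.33 (adjusted p = 1). Both probe sets were higher in 3 of 3 experiments, by 1.05 and 0.68 in A, 0.10 and 0.04 in B, and 0.55 and 1.87 in C. With the replicate block, limma's unadjusted p was 0.109 and 0.0539 (adjusted p = 0.931 for both). The labels do not say whether these probe sets detect the transcript of the cassette. Actb, the reference gene, had a log2 fold change of 0.01.

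**Figure D2:**
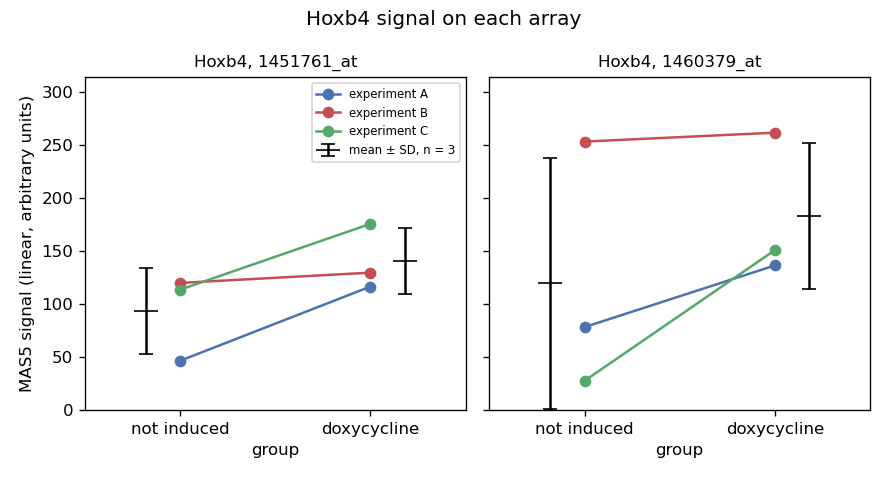
MAS5 signal (linear, arbitrary units) of the 2 Hoxb4 probe sets on each array; coloured lines join the uninduced and induced arrays of each experiment, and black bars give the mean ± SD of each group (n = 3). On both probe sets the line of experiment B is nearly flat, from 119.8 to 129.5 and from 253 to 261.4.

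No gene rose or fell with doxycycline past the threshold. With limma, 0 probe sets were higher and 0 lower of 27022 tested, the smallest adjusted p being 0.99996. At an unadjusted p under 0.05 there were 77 higher and 69 lower, 146 in all. With the replicate block the counts were again 0 and 0 (smallest adjusted p 0.931), with 521 higher and 550 lower at an unadjusted p under 0.05, 1071 in all. Simulated data with no change and with noise independent between probe sets gave 70 such probe sets without and 1395 with the block. In these data 0 and 2 probe sets passed the adjusted threshold. The median half-width of the 95% confidence interval was 0.80 log2 units, and 0.56 with the block. Across probe sets, which are not independent replicates, the differences between induced and uninduced arrays correlated at -0.03 between A and B, -0.02 between A and C and 0.09 between B and C. The difference had the same sign in 3 of 3 experiments for 25.9% of the probe sets, where chance gives 25%. With the sign turned in A, B or C this share was 29.6%, 22.6% and 21.7%.

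The genes with the smallest p are given because none passed. On the higher side, Dpf3, which encodes a subunit of a chromatin remodelling complex, had signals of 35.7 ± 16.5 (SD, n = 3) without and 164.7 ± 81.8 (SD, n = 3) with doxycycline, a log2 fold change of 1.70 with an interval of 0.70 to 2.70. The others were Capn1, which encodes a calcium-dependent protease, at 1.36, the methyltransferase gene Eef1akmt1 at 1.30, Efcab1 at 1.15 and Amdhd2 at 0.80. On the lower side, Lratd2 had signals of 559.7 ± 79.2 (SD, n = 3) without and 261.4 ± 43.65 (SD, n = 3) with doxycycline, a log2 fold change of -1.05 with an interval of -1.66 to -0.44. Azi2 stood at -1.25, Itgb3bp at -1.14, Tox4 at -1.04 and Bcl2l11, which encodes the cell death protein BIM, at -0.88. All 10 genes had the same sign in 3 of 3 experiments and an adjusted p of 1. Other tested probe sets pointed the opposite way for Efcab1 (2 of 2), Bcl2l11 (2 of 4) and Itgb3bp (1 of 3).

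Differences of over 2-fold in the same direction in all 3 experiments were found on 8 probe sets, 6 higher and 2 lower; turning the sign in A, B or C gave 14, 6 and 6. The higher ones, named after their values were seen, were those of Dpf3, Ppp1r13l, Fbxw16, Gp5, 1810021B22Rik and B230311B06Rik. The lower ones were a probe set of Zbed6, at -1.73, -1.14 and -1.61 in A, B and C, and a probe set for which no gene name was used. Within single experiments, differences of over 2-fold covered 10.9% of the probe sets in A, 3.96% in B and 6.00% in C.

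No blood gene list passed the camera threshold when HOXB4 was induced. Of 23 tested haematopoietic stem and progenitor regulators, 15 had a higher and 8 a lower point estimate, with a mean log2 fold change of 0.10 (camera, adjusted p = 0.662). Runx1, a master regulator of definitive blood formation, stood at -0.84 with an interval of -1.69 to 0.01, lower in 3 of 3 experiments, although its other tested probe set pointed the opposite way. For Runx1 limma's unadjusted p was 0.0531 without and 0.0376 with the replicate block (adjusted p = 0.931 with the block). Spi1, the myeloid regulator PU.1, stood at 0.70 and Zfpm1, the GATA1 partner FOG1, at 0.65. Of 19 erythroid and haem synthesis genes 12 were higher and 7 lower, with a mean of 0.06 (adjusted p = 0.662): the erythrocyte spectrin gene Sptb at 0.48, Icam4 at 0.43 and the tropomodulin gene Tmod1 at -0.73. Of 13 myeloid and macrophage genes 8 were higher and 5 lower; the median was 0.02 while the mean of -0.05 and the test pointed down (adjusted p = 0.654), with Ptpn6 at 0.56, Laptm5 at -0.68 and Ncf1 at -0.42. Single arrays change these calls: the stem and progenitor mean was 0.49 without the uninduced array of B (adjusted p = 0.000802) and 0.39 without the induced array of C (adjusted p = 0.00947), and the erythroid mean was 0.52 without the uninduced array of B (adjusted p = 0.0022), all past the threshold. Without the induced array of B they were -0.19 and -0.27 (adjusted p = 0.105 for both). Leaving out 1 array, here and below, unbalances the experiments between the groups, so that differences between experiments enter the doxycycline comparison. With both arrays of B left out, the stem and progenitor mean was 0.21 (adjusted p = 0.158) and the erythroid mean 0.17 (0.254). With both arrays of C left out they were 0.24 (0.124) and 0.15 (0.635), none past the threshold.

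Of 12 megakaryocyte and platelet genes 9 were higher and 3 lower, with a mean of 0.16 (adjusted p = 0.594). It was -0.033 without the uninduced array of A, -0.039 without the induced array of B, and 0.33 without the induced array of A or the uninduced array of B, none past the threshold. Gp5, a platelet membrane glycoprotein gene, had signals of 44.6 ± 30.2 (SD, n = 3) without and 122.6 ± 69.4 (SD, n = 3) with doxycycline, a log2 fold change of 1.15 that was higher in 3 of 3 experiments, by 1.01, 1.27 and 1.17, with an adjusted p of 1. F10 stood at 0.39 and the platelet factor gene Pf4 at 0.48. With the replicate block and fry, a setting added after the data had been seen that does not set a list against other genes, this was the only list of 23 past the threshold (adjusted p = 0.0197); camera with the block gave 0.346.

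Of 32 endothelial genes 21 were higher and 11 lower, with a mean of 0.09 (adjusted p = 0.654), but 0.69 without the uninduced and -0.51 without the induced array of B, and 0.67 without the induced array of C, each past the threshold. With both arrays of A, B or C left out, the endothelial mean was -0.12, 0.07 and 0.38, only the last past the threshold (adjusted p = 0.0202). The arterial and venous pair Efnb2 and Ephb4 stood at -0.59 and 0.52, and the gap junction gene Gja4 at 0.68. Markers of other lineages gave means between -0.19 and 0.18, none past the threshold on all 6 arrays. Without the induced array of C they passed at 0.56 for cardiac, -0.91 for neural, 0.55 for mesenchymal, 0.75 for endoderm and 0.34 for primitive streak genes. Without the uninduced array of C cardiac genes were at -0.82 and endoderm genes at -0.45, also past it. Without the uninduced array of B neural genes passed at -0.94, mesenchymal genes at 0.72 and endoderm genes at 0.42, and without the induced array of B cardiac genes at -0.66. When both arrays of an experiment were left out, only primitive streak genes among these lineages passed, at 0.35 without C (adjusted p = 0.0202). Among 22 cardiac genes 14 were lower, with a mean of -0.17 (adjusted p = 0.382), Myh7 at -0.40, Myh6 at -0.49 and Nkx2-5 at -0.53. Among 28 neural and neural crest genes 18 were lower, with a mean of -0.19 (adjusted p = 0.382), the proneural gene Neurod1 at -1.33, Pax6 at -0.90 and Elavl3 at -0.81. Among 22 mesenchyme, smooth muscle and fibroblast genes 15 were higher, with a mean of 0.18 (adjusted p = 0.301), Pax9 at 1.01, Foxc2 at 0.87 and Tcf15 at 0.65. Among 28 endoderm genes 21 were higher, with a mean of 0.13 (adjusted p = 0.637), Vil1 at -1.16, Ihh at 0.74 and Apoa2 at 0.75. The 22 pluripotency genes had a mean of 0.09 (adjusted p = 0.654), with Lefty1 at 1.03, Klf2 at 0.54 and Pou5f1 at -0.53, and the 20 primitive streak and early mesoderm genes one of 0.15 (adjusted p = 0.654), with Cdx2 at 0.40, Fgf17 at 0.52 and Mesp2 at 0.34.

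With the filter used here, the largest mean among the 23 lists was that of the Hox cluster, the family HOXB4 belongs to. When no filter was applied the Hox mean was 0.14. It then lay below those of the Wnt (0.18), primitive streak (0.17), mesenchymal (0.17) and FGF (0.17) lists. Of 17 tested Hox genes 11 were higher and 6 lower, with a mean of 0.31 (adjusted p = 0.301, and 0.0509 with the replicate block). By experiment the mean was 0.83 in A, 0.15 in B and -0.04 in C. With 1 array left out it was -0.13 without the uninduced array of A and -0.16 without the induced array of B, but 0.82 without the uninduced array of B (adjusted p = 2.89e-05), 0.50 without the induced array of A (0.0488) and 0.60 without the induced array of C (0.00468), the last 3 past the threshold. With both arrays of A, B or C left out, the Hox mean was 0.05, 0.39 and 0.49, only the last past the threshold (adjusted p = 0.0202). Hoxb1 stood at 0.81 and Hoxc6 at 0.73, beside Hoxb4 itself. The 9 TALE cofactors, which bind DNA with Hox proteins, had a mean of 0.10 (adjusted p = 0.637), with Meis3 at 0.50, Pknox1 at 0.24 and Pbx2 at 0.13.

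No signalling or growth list passed the threshold on all 6 arrays. The mean was 0.17 for 22 Wnt genes (adjusted p = 0.615), with Sfrp5 at 0.43, Lgr5 at 0.40 and Fzd10 at 0.71. It was 0.09 for 20 Notch genes (adjusted p = 0.654), with Rbpj at -0.35, Jag2 at 0.51 and Heyl at -0.47, and 0.04 for 24 BMP and TGF-beta genes (adjusted p = 0.746), with Msx1 at 0.55, Acvrl1 at 0.70 and Msx2 at 0.35. It was 0.12 for 17 FGF genes (adjusted p = 0.654), with Fgf3 at 0.64, Etv5 at 0.47 and Fgfr4 at 0.33. For 13 TNF and NF-kappaB genes the mean was 0.01, while the median of -0.02 and the test pointed down (adjusted p = 0.954), with Birc3 at 0.78, Traf2 at 0.30 and Tnfaip3 at -0.33. The 21 genes of the integrated stress response had a mean of 0.04 (adjusted p = 0.654), with Asns at 0.34, Ddit3 at -0.54 and Psat1 at 0.43. For 31 cell cycle genes the median was 0.03, while the mean of -0.0029 and the test pointed down (adjusted p = 0.654); Mki67 stood at -0.26, Cdt1 at -0.29 and Tyms at -1.11. Leaving out 1 array took 4 of these lists past the threshold: Wnt at 0.49 (adjusted p = 0.00829) and Notch at 0.37 (0.0339) without the induced array of B, FGF at 0.53 (0.000946) without the uninduced array of C and cell cycle at -0.072 (0.0378) without the induced array of C. When both arrays of an experiment were left out, Wnt and Notch did not pass. FGF passed at 0.30 without C (adjusted p = 0.0202) and cell cycle at -0.039 without A (0.0479).

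In 3 lists the members lay lower with doxycycline past the camera threshold at the preset correlation, each with an adjusted p of 0.0451. Immediate early and heat shock genes had a mean log2 fold change of -0.27, with 14 of 17 members lower, and means of -0.26 in A, -0.38 in B and -0.16 in C (adjusted p = 0.834 with an estimated correlation). Its members with the smallest p were the antiproliferative gene Btg2 at -0.66, the heat shock gene Hspa1b at -1.34 and its cochaperone gene Dnajb1 at -0.23. The p53 targets had a mean of -0.21, with 12 of 14 members lower (adjusted p = 0.914 with an estimated correlation); the mean was -0.66 in A, -0.0076 in B and 0.05 in C. Ccng1 stood at -0.43, Bbc3, which encodes PUMA, at -0.29 and Pmaip1, which encodes NOXA, at -0.27. Hypoxia and glycolysis genes had a mean of -0.14, with 14 of 18 members lower (adjusted p = 0.914 with an estimated correlation), made of 0.41 in A, -0.25 in B and -0.59 in C. The glucose transporter gene Slc2a1 stood at -0.32, Pdk1 at -0.31 and Higd1a at -0.22.

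Each of these 3 calls was lost when certain single arrays were left out, although the immediate early mean stayed between -0.18 and -0.39 without any 1 array. Without the uninduced array of A, the one with the high 3' to 5' ratio, the mean of the p53 targets was -0.0097 (adjusted p = 0.885), and without the induced array of A it was -0.18 (adjusted p = 0.136). The hypoxia list was no longer past the threshold without the uninduced array of B (0.07, adjusted p = 0.77), the uninduced array of C (-0.13, 0.301) or the induced array of C (0.07, 0.814), nor the immediate early list without the uninduced array of B (-0.22, 0.44) or the induced array of C (-0.19, 0.162). The number of lists past the threshold, higher or lower, was 8 and 7 without the uninduced and induced arrays of B and 5 and 10 without those of C. Among the members of all 23 lists, limma called 0 genes adjusted over all probe sets and 0 adjusted over the list alone, with and without the block; at an unadjusted p under 0.05, without the block, there were 2, Gp5 and Btg2, and with the block 33. Apart from genes already said to disagree, another tested probe set pointed the opposite way for Sptb, Laptm5, Efnb2, Pbx2, Cdt1, Rbpj, Jag2, Fgfr4, Psat1, Higd1a, Dnajb1 and Actb.

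**Figure D3:**
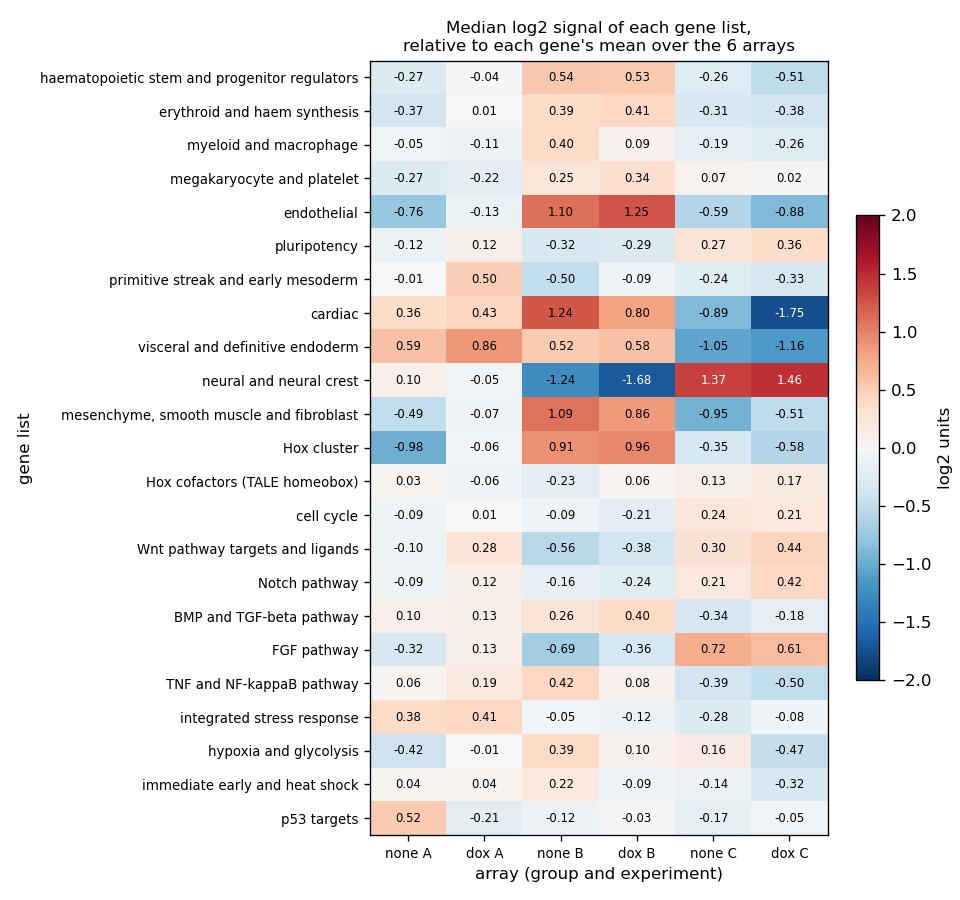
Median log2 signal of each of the 23 gene lists on each array, relative to each gene's mean over the 6 arrays (colour and printed value, log2 units; columns are arrays, "none" uninduced and "dox" induced, with the experiment letter). The endothelial list stands at 1.10 and 1.25 in experiment B and at -0.59 and -0.88 in C, and the neural list at -1.24 and -1.68 in B and at 1.37 and 1.46 in C.

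The second comparison, added after the data had been seen, set the 3 experiments against one another, whatever the induction. By camera at the preset correlation the endothelial, stem and progenitor regulator, erythroid, cardiac and mesenchymal lists were higher in B than in A and C, and the neural list was higher in C than in A and B. With an estimated correlation none of these differences passed, and the smallest adjusted p was 0.243 with an estimated correlation. That loss does not by itself show a high correlation between the genes of a list. For the neural list the estimated correlation was -0.0174, below the preset 0.01. Camera's unadjusted p in C against B was nevertheless 1.98e-16 with the preset and 0.0114 with the estimated correlation. By limma's F test 3071 probe sets (11.4% of those tested), which represent 1688 genes, differed between experiments, and 2525 differed between C and B, 1136 higher and 1389 lower in C. The count of 3071 depends on every array: it was 8572 without the uninduced and 13645 without the induced array of A, 1484 and 1720 without those of B, and 1513 and 1495 without those of C. The letters name experiments whose differences the labels do not describe. Each experiment entered with only its induced and its uninduced array. The p values of this comparison therefore refer to the spread between those arrays and not to repeats of an experiment.

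Among the leading genes, Otx2, a forebrain and midbrain regulator, was lower in B than in A by a log2 difference of at least -5.49 and higher in C than in B by at least 5.24 (adjusted p = 0.000236 and 3.68e-05). Both are bounds, since its level in B lay below the 6.19 log2 units under which probe sets were not tested. The neural stem cell factor gene Sox2 was higher in C than in B by 3.97. En2, Pax3 and Wnt1, genes of the midbrain, neural crest and midbrain border with levels in B below the same limit, were higher in C by at least 4.59, 4.14 and 3.86. In the other direction C stood below B by at least -6.11 for Tnni1, the slow skeletal and fetal heart troponin gene, whose level in C lay below that limit, by -5.37 for the heart regulator gene Hand2 and -4.59 for Tbx20. The endoderm genes Ttr and Spink1 were lower in C than in B by -6.28 and -5.20, and the epithelial keratin genes Krt8 and Krt18 by -3.37 and -3.03. Other leading genes were Prdm6 at -5.04, Stard8 at -4.76, Dlk1 at -4.80, Apela at -3.96, Pmp22 at -3.91, Ahnak at -3.89 and Tgfb2 at -4.27, all lower in C than in B, and Cntnap2 at 4.87, Ildr2 at 4.72, Dtx4 at 4.22 and Crabp2 at 3.62, all higher.

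Endothelial genes were called higher in B than in A in 12 cases and lower in 1 of 32, with a mean of 1.61. C lay below B by a mean of -2.05, with 22 called lower and 1 higher. The receptor gene Tek, which marks vessels, was 3.37 above A in B and -3.97 in C against B, Sox18 3.06 and -3.91, and Nrp1 1.56 and -4.30. The 23 stem and progenitor regulators had a mean of 0.87 in B against A and -1.02 in C against B, with 4 called higher and 9 called lower, among them Mecom at 2.35 and -2.17 and Fli1 at 1.90 and -2.47. Embryonic globin genes differed most in the erythroid list, whose mean was 1.15 in B against A: Hba-x was 4.76 and Hbb-bh1 4.52 higher in B than in A, and -4.65 and -4.43 in C against B. Without the uninduced array of A, Hba-x was 3.51 and Hbb-bh1 2.75 higher in B than in A. The Hox cluster had a mean of 1.64 in B against A and -1.41 in C against B, with Hoxd9 at 3.06 and -3.87 and Hoxb6 at 2.90 and -3.12. With an estimated correlation the adjusted p of these lists was 0.318 to 0.351 in B against A and 0.318 to 0.372 in C against B.

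Mesenchymal genes had a mean of 1.33 in B against A and -1.79 in C against B, with Col3a1 at 4.67 and -3.42, Postn at 4.81 and -5.36 and the epithelial to mesenchymal transition gene Snai2 at 1.79 and -4.97. Cardiac genes had a mean of -2.34 in C against B, with 13 of 22 called lower, and endoderm genes one of -1.74, with 17 of 28 called lower. Neural and neural crest genes had a mean of -1.63 in B against A, with 9 called lower, and 2.94 in C against B, with 21 of 28 called higher and 0 lower. FGF genes (mean 1.10) and Wnt genes (mean 0.99) were also higher in C than in B, among them Spry1 at 2.75, Fgf8 at 3.14 and Sp5, whose level in B lay below 6.19 log2 units, at 3.46 or more. With an estimated correlation the adjusted p was 0.243 for the neural, cardiac and endoderm lists, 0.275 for the mesenchymal list and 0.318 for the FGF and Wnt lists.

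Between C and B, camera at the preset correlation placed 6 lists higher in C and 9 lower, and with an estimated correlation 0 and 0; over the 3 pairwise contrasts the smallest adjusted p with an estimated correlation was 0.243. By the F test none of the 9 TALE cofactors passed, while 1 of 31 cell cycle genes did, Ccne1, at 1.03 in C against B. The cell cycle list was nevertheless among the 6 lists higher in C, with a mean of 0.31 (camera, adjusted p = 0.00132). In that contrast 2 of its members were called higher and 0 lower.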

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

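The settings that leave out both arrays of an experiment, median centring, the offsets and the 60th percentile filter for the lists, the replicate block without an intensity trend, with an estimated correlation or with fry, and every setting of the comparison of experiments were chosen after seeing the data. Under each of the 19 settings run for the probe set counts, limma called 0 probe sets higher and 0 lower with doxycycline; without a filter, 846 probe sets had an unadjusted p under 0.05, and with the replicate block 1071. The fold changes of the 80 named genes crossed no threshold in 1493 alternative values and changed sign in 25. The replicate block left the 3 list calls in place and changed no other camera call. Signal over background limits what dim probe sets show, since the table holds no detection calls.

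The number of lists past the threshold was 3. It was 0 without a filter, 0 with an estimated correlation, 0 with fry, 0 with the replicate block and an estimated correlation, 1 with the replicate block and fry, and 1 with the mean of all probe sets of a gene; leaving out arrays or experiments gave 1 to 10, with fewer arrays in the fit. For hypoxia and glycolysis the mean was -0.13 with quantile normalization, -0.16 with median centring, -0.16 without a filter and -0.089 with the mean of all probe sets, none of them past the threshold. For immediate early and heat shock genes it was -0.24 without a filter and -0.24 with the mean of all probe sets, and for p53 targets -0.18 without a filter, again not past it. The means stayed at -0.14, -0.27 and -0.21 with an estimated correlation, with fry, and with the replicate block in either of these, but no longer passed. For the immediate early list the estimated correlation without the block, -0.0033, lay below the preset 0.01. Camera's unadjusted p still rose from 0.00401 to 0.0362, which argues against a higher correlation between its genes as the reason. Beyond that, the cause was not tested. Leaving out arrays or experiments moved the hypoxia mean from -0.42 to 0.082, the immediate early mean from -0.39 to -0.18 and the p53 mean from -0.36 to 0.020.

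Of 418 alternative values of the other 20 lists, 66 changed direction and 30 passed the threshold. In 3 lists a value passed in the direction opposite to that reported: the endothelial mean ranged from -0.51 to 0.69, the cardiac mean from -0.82 to 0.56 and the endoderm mean from -0.45 to 0.75 when arrays were left out. Each of these extremes came from leaving out an array of B or C, which unbalances the experiments between the groups. The number of probe sets that differ between experiments, 3071, was 1141 without the intensity trend and ranged from 1070 to 13645 when arrays or experiments were left out; the cause was not tested.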

Other observations

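In the paragraphs on explanations below, the splits of probe set counts, the estimated correlation, the admixture and RNA quality tests and the tests of the experiment differences were chosen after the results were seen. The induced array of experiment A held levels between those of B and C for most lists. Its list median lay between the means of B and C in 18 of 23 lists, and that of the uninduced array of A in 14 of 23. Tnni1, a gene of the early heart, stood at 10.26 log2 units on the induced array of A, 12.28 on that of B and 4.95 on that of C, while Otx2, the forebrain and midbrain gene, was an exception at 11.45, above the 5.76 of B and the 11.32 of C. Embryonic globin was among the genes that differed between the arrays of A: Hbb-bh1 stood at 8.47 on the uninduced and 11.44 on the induced array of A, but at 14.70 and 14.25 in B and 10.40 and 9.68 in C. Fli1, a regulator of blood and endothelium, stood at 5.87 and 7.26 in A, 8.40 and 8.54 in B and 5.75 and 6.26 in C.

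Single genes of other lists also differed between experiments. Dll1 and Hes5 of the Notch pathway were higher in C than in B by 3.14 and 2.88 (adjusted p = 0.000358 and 0.00103 for this contrast), and the FGF feedback genes Dusp6 and Il17rd by 2.05 and 2.56 (adjusted p = 0.00133 and 0.00195). Bmp4 and Bmp2 were lower in C than in B, at -2.73 and -3.42, as were the hypoxia gene Ndrg1 at -3.08, the stress gene Trib3 at -2.13 and Perp at -1.84. Of the 22 pluripotency genes 5 were called higher and 1 lower in C than in B, with a mean of 0.69. The list passed camera at the preset correlation (adjusted p = 0.0162) but not with an estimated one (0.318). By limma, Dppa5a was higher by 1.89 (adjusted p = 0.0211), while Tbx3 was the member called lower, at -2.58 (adjusted p = 0.00423).

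The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 0 probe sets, and the highest of the others also 0. For lists past the threshold the real split gave 3 and the highest of the others, which sets both arrays of B and the uninduced array of A against the rest, gave 16; 8 of 10 splits gave at least as many, which points to a structure of the arrays by experiment. Among the 4 splits that part all 3 pairs, the blocked fit gave 3 lists for the real one and 7, 2 and 7 for the others, which differ in having the induced and uninduced arrays of 1 experiment exchanged.

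Without the uninduced array of A, 2 of the 3 lists lower with doxycycline still passed, while the p53 list did not. For the immediate early list, at -0.18 (camera, adjusted p = 0.0425), this argues against that array as the sole cause. With both arrays of A left out this list also passed, at -0.27 (0.00667). For the hypoxia list leaving out that array could not decide. Its mean was 0.41 higher with doxycycline in A, so that array had worked against the call. With an estimated correlation 0 of the 3 passed, but no list passed between the experiments with an estimated correlation either, so that test cannot tell whether the correlation between the genes of a list made the calls. The estimated correlation was 0.485 for the hypoxia and 0.143 for the p53 list and -0.0033 for the immediate early list, against the preset 0.01. A candidate explanation for the hypoxia and p53 calls is therefore shared variation of their genes between arrays; for the immediate early and heat shock list, which was lower in 3 of 3 experiments, a response to HOXB4 or to doxycycline stays open.

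For the induced array of A between the experiments, RNA of B and C mixed into it as the whole cause is argued against: signals of probe sets high in B alone or C alone stood at a median share of 0.0841, below the fitted weights of 0.311 for B and 0.264 for C. A smaller admixture stays open. For degraded RNA on the uninduced array of A, the spread of the induced array's differences from B and C was at most 0.776 of that between B and C. These values hold nothing from the uninduced array, so its RNA could not have changed them and they do not test this explanation. They show only that the induced array lay nearer to B and to C than these lay to one another. A compressed signal range cannot be told apart: 5 other arrays had a lower standard deviation of log2 signal over all probe sets, but 0 did over the tested ones, so the bound set beforehand on all probe sets was too weak. An intermediate mix of cell types in experiment A may also give this picture and was not tested.

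For the marker lists that differ between experiments, a scaling or labelling difference that shifts all lists alike was set against the single genes of the lists. Limma called 59 members higher and 124 lower in C than in B, so that 32.2% went in the rarer direction and the members did not all shift alike. Every array had been scaled to a trimmed mean of 500 before deposit, which largely takes out such a shift beforehand. A labelling difference that acts unevenly on the genes is not covered by this count. Degraded RNA of the uninduced array of A is argued against by the 2525 probe sets that differ between B and C, neither of which involves that array. The 3' signal of the spike control Dap also differed between experiments. Without and with doxycycline it was 488 and 295.3 in A, 157.2 and 134.2 in B, and 82.3 and 72.1 in C. Other technical differences between the experiments were not tested. The experiment is the replicate of the design, and no biological explanation was tested; embryoid bodies that had reached different mixes of lineages by day 6 are a hypothesis that these values leave open.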
